A study of Mus musculus with 2 samples.

How the data were processed

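The samples were tuft cells sorted from the small intestine of mice by flow cytometry as cells positive for EpCAM, an epithelial surface protein, and Siglec-F, a lectin that marks intestinal tuft cells. Tuft cells are rare chemosensory cells of the gut epithelium. One library came from mice with an intact Spib gene that carried Villin-cre, called WT here, and one from mice with floxed Spib and Villin-cre, called Spib_KO here. Villin-cre expresses Cre recombinase in the intestinal epithelium. The labels give neither the number of mice behind each library nor the part of Spib that is deleted. Per the labels' protocols, RNA was extracted with TRIzol, cDNA was amplified by a Smart-seq2 type method and libraries were made with a transposase. No molecular identifiers are named, and this chemistry does not keep strand.

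Per the submitters' processing notes, the authors used HISAT and Bowtie2 2.2.3 with the mouse build mm10. The program that counted reads and its annotation are not given in the sources used here. Per the file headers, the authors deposited a read count, an FPKM value and a TPM value for each of 17134 genes in each library. The deposited read counts are expected counts, since 19.0% of genes in the WT library and 18.6% in the Spib_KO library have a value that is not whole. They were rounded to whole numbers. The deposited TPM and FPKM values were used only as alternatives. The table holds no mitochondrially encoded gene. Every row has a gene symbol, and each column of values was matched to 1 of the 2 libraries.

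Library sizes were scaled with TMM factors from edgeR 4.0.16 in R 4.3.3, giving effective totals of 17996059 for WT and 17161039 for Spib_KO. Normalised read counts (CPM) were counts scaled to a common library size by these totals. The log2 ratio was Spib_KO over WT with a prior count of 0.5 per library, scaled to library size. Its 95% interval was the exact conditional binomial (Clopper-Pearson) interval of the pair of counts. Intervals of single CPM values were exact Poisson intervals. Amplified reads without molecular identifiers are not independent molecules, so all intervals and floors cover counting error only. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots used matplotlib 3.10.9.

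With 1 library per genotype no test between genotypes was possible, and no p-value is given. A fixed rule of size was used in its place. A gene was measured if it had a CPM of 5 or more and 30 reads or more in at least 1 library. It was called higher or lower if the bound of its interval nearest 0 was at least 1 on the log2 scale, a 2-fold difference. For a gene with 0 reads in a library, the fold was computed against a floor of 3 counts in that library and is written as "at least". Values of genes with 1 to 3 reads in a library are given with their counting interval.

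The size rule, the alternatives, 38 gene lists and the rule for naming genes were fixed before the data were examined. Ribosomal protein genes and mitochondrially encoded genes were added as 2 lists by symbol. For each list with 4 or more measured members, the median log2 ratio was placed among 10000 random lists of the same size matched on mean CPM in 20 bins. That percentile describes these libraries and is not a p-value. Medians did not change at 2 decimals when genes at 0 were set to their floor. The genes named were Spib, Epcam and Siglecf, the 12 furthest above and the 12 furthest below by the interval bound nearest 0 among genes with a CPM of 20 or more, up to 4 called members of each list (or the 2 most abundant members where none was called), and the 5 genes with the most reads in each library. The second of these parts left out predicted and RIKEN clones and ribosomal protein, haemoglobin and antigen receptor genes. Other genes named in the report (Dclk1, Trpm5, Il25, Alox5, Chat, Sst, Chga, Gip, Duoxa2, Lyz1, Defa24, Itln1, Ang4, Mcpt1, Cpa3 and the genes that overlap a named gene) were chosen after their values were seen, as were those of the closing section except the genes of 2 tests named there.

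Coordinates are from a RefSeq gene table of GRCm38.p6, the assembly that mm10 stands for. Of the 17134 gene identifiers, 17087 had a position there. Because strand is not kept, reads of overlapping genes cannot be told apart, and near-identical genes such as the alpha-defensins share reads. Such genes are pointed out where they are named.

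The procedure was tested on simulated data drawn from the counts of the 17134 genes of the comparison of Spib_KO with WT, with 200 genes changed by a known factor. With counting error alone, 92.0% of genes changed 2.5-fold, 94.0% of those changed 4-fold and 100% of those changed 8-fold were called. None of 50 genes changed 1.5-fold and 0 of 10250 unchanged genes were called. When each gene of each library also varied with a coefficient of variation of 0.2, 57 of 10298 unchanged genes were called, which is 0.55%. At a coefficient of variation of 0.4 it was 1713 of 10360, or 16.5%. Recovery moved too. Of genes changed 2.5-fold, 64.0% were called at a coefficient of variation of 0.2 and 56.0% at 0.4, and of genes changed 4-fold 98.0% and 80.0%, and of genes changed 8-fold 96.0% and 98.0%. Genes changed 1.5-fold, under the rule, were called in 8.0% and 26.0%. The 1713 calls at 0.4 exceed the 250 higher and 233 lower genes of the data, so 0.4 for every gene is more than these libraries show. The variation between animals or amplifications in this study is unknown, so how many of the called genes would be called again cannot be given.

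Alternatives were DESeq2 1.42.0 size factors, total counts, upper-quartile scaling, totals without the 20 most abundant genes, scaling on the tuft identity list, other expression filters, a prior count of 5, thinning of the deeper library, other size rules, removal of ribosomal protein and haemoglobin genes, and log2(value + 1) differences of the deposited TPM and FPKM. Leaving out a replicate was not possible. Some genes that the naming rule selects are not reported here.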

Results

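RNA sequencing was carried out on tuft cells sorted from the small intestine of untreated mice, with 1 library from WT mice and 1 from Spib_KO mice, in which Villin-cre deletes floxed Spib in the intestinal epithelium. Spib encodes Spi-B, a transcription factor of the ETS family known from B cells and intestinal M cells. The WT library held 17925421 reads assigned to genes and the Spib_KO library 17228665. Reads were found for 16085 and 15437 genes, and the 10 most abundant genes took 8.8% and 9.9% of the reads. The comparison asks which transcripts of sorted tuft cells differ when Spib is deleted in the epithelium. There was no replicate check for any difference below, and each value describes these 2 libraries.

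Spib itself (gene 272382, chromosome 7, 44525995 to 44532087, GRCm38.p6) was almost lost from the Spib_KO library. It had 6266 reads in WT, or 348 CPM (95% Poisson interval 340 to 357), and 48 reads in Spib_KO, or 2.80 CPM (2.06 to 3.71). The log2 ratio was -6.95 (95% interval -7.40 to -6.55), which leaves 0.81% of the WT level (0.59% to 1.07%). The genes used for the sort were close in both libraries. Siglecf had 953 CPM in WT and 1048 CPM in Spib_KO, a log2 ratio of 0.14 (0.11 to 0.17). Epcam had 1722 and 1653 CPM, a log2 ratio of -0.06 (-0.08 to -0.04).

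**Figure D1:**
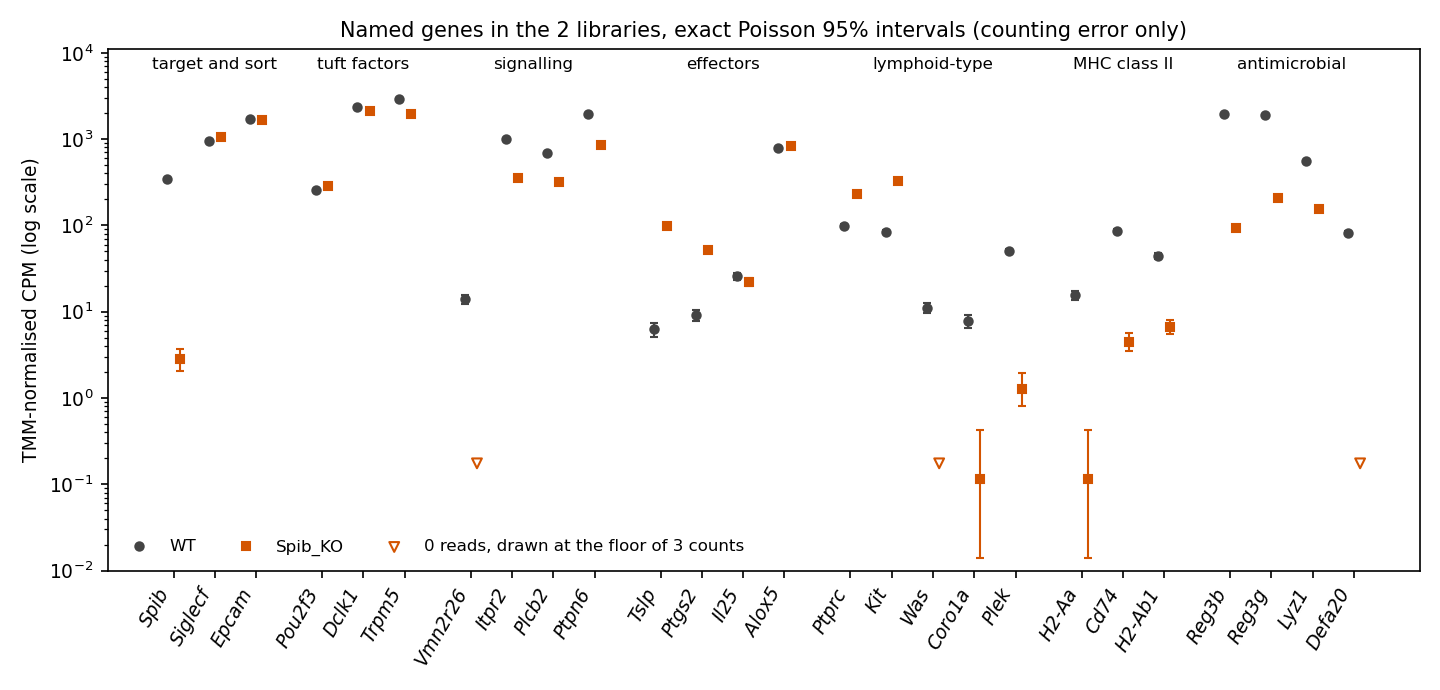
Normalised read counts (CPM, log axis) of named genes in the WT library (circles) and the Spib_KO library (squares), with exact Poisson 95% intervals that cover counting error only. Open triangles stand for 0 reads, drawn at the floor of 3 counts. Spib lay at 348 CPM in WT and 2.80 CPM in Spib_KO, whereas Siglecf and Epcam lay close together in both.

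Most transcripts were at similar levels. Of 10707 measured genes, 250 (2.33%) were higher and 233 (2.18%) were lower in Spib_KO by the rule of a 2-fold difference. The median log2 ratio was 0.01, with quartiles of -0.26 and 0.28, and 79.5% of genes differed by less than 1.5-fold. At a 4-fold bound, 65 genes were higher and 88 lower. Without defensins and the genes of the lists of other cell types, a choice made after seeing the data, 247 were higher and 192 lower. The counts move with the thresholds. Without the expression filter they were 595 and 716, and with a CPM minimum of 20 they were 101 and 106.

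**Figure D2:**
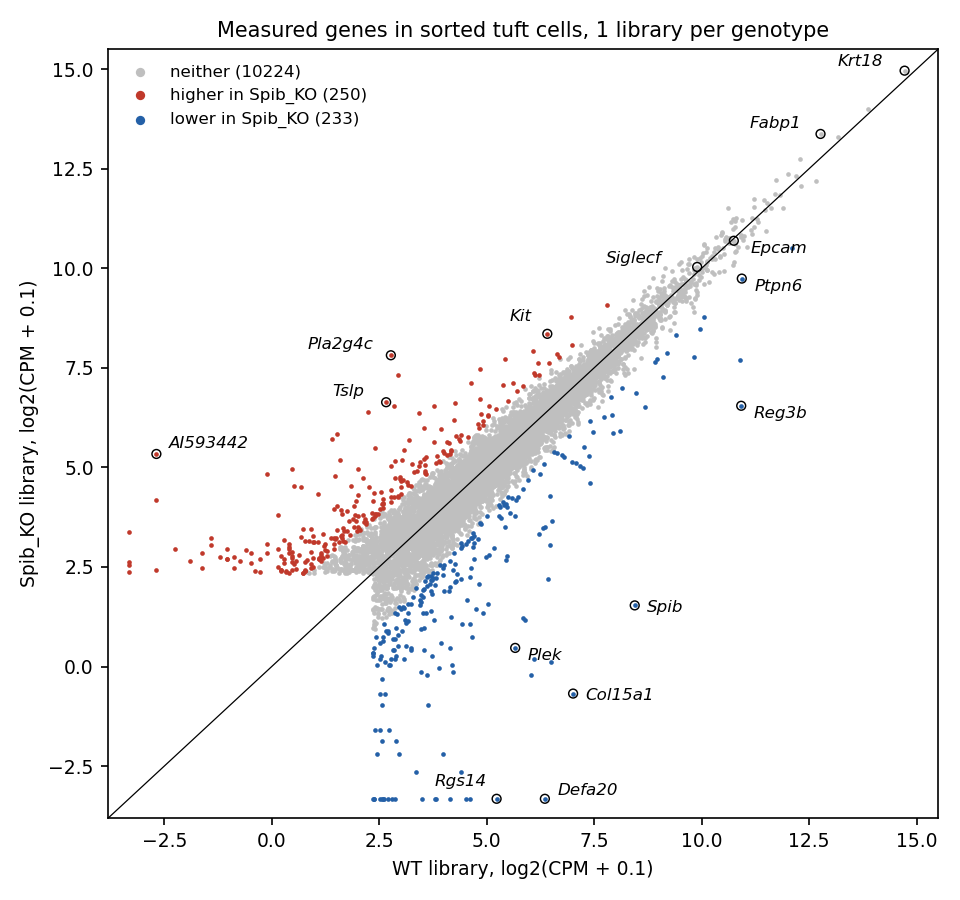
Level of each measured gene in the WT library (x axis) and the Spib_KO library (y axis), as log2(CPM + 0.1), with the line of equal levels. Red points are the 250 genes called higher and blue points the 233 called lower in Spib_KO, and circled points carry their gene symbol. Most genes lie along the line, whereas Spib, Col15a1 and Defa20 lie far below it and Pla2g4c and Tslp far above it.

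Most tuft cell genes were at similar levels in both libraries. Of 35 measured tuft identity genes, 34 were neither higher nor lower, and the median log2 ratio was 0.02, at the 55.6th percentile of random lists. Pou2f3, the transcription factor required for tuft cells, had 256 CPM in WT and 287 CPM in Spib_KO, a log2 ratio of 0.17. Dclk1, a kinase used as a tuft marker, had 2369 and 2100 CPM, a ratio of -0.17. The cation channel gene Trpm5 had 2891 and 1964 CPM, a ratio of -0.56. The exception was Ptpn6, which encodes the tyrosine phosphatase SHP-1. It fell from 1958 to 856 CPM, a log2 ratio of -1.19 (-1.22 to -1.17). Neither tuft-1 genes, named after a more neuronal tuft subset, nor most tuft-2 genes, named after a more immune subset, passed the rule. Of 6 tuft-1 genes 0 were called and the median log2 ratio was 0.19, while of 11 tuft-2 genes 2 were higher, Tslp and Ptprc, and the median was 0.18, both within the central 95% of random lists. Ptprc, which encodes the phosphatase CD45, rose from 98.7 to 229 CPM, a log2 ratio of 1.22 from 1777 and 3935 reads.

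Among genes for what tuft cells secrete, 3 of 13 measured members were higher and 0 lower, where the share over all genes gives 0.30 higher. The list median was 0.15 (89.1st percentile). Tslp, which encodes an epithelial cytokine, rose 15.9-fold, from 6.22 to 99.4 CPM, a log2 ratio of 3.99 (3.72 to 4.29). Ptgs2, the inducible cyclooxygenase, rose 5.67-fold, from 9.06 to 51.5 CPM (95% interval of the log2 ratio 2.26 to 2.76). Slc18a3, the vesicular acetylcholine transporter, rose from 72 to 185 reads, a log2 ratio of 1.42 (1.03 to 1.84). It lies within Chat, whose log2 ratio was 0.01, and unstranded reads do not separate the pair. The cytokine gene Il25 had 25.6 and 22.1 CPM, a log2 ratio of -0.21, and the lipoxygenase gene Alox5 had 790 and 838 CPM, a ratio of 0.09.

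Taste-type chemosensory genes went both ways. Of 12 measured members 3 were lower and 1 higher, with a median of -0.15 (8.0th percentile). Itpr2, an inositol trisphosphate receptor gene, fell 2.82-fold, from 995 to 353 CPM (95% interval of the log2 ratio -1.54 to -1.45). Plcb2, the phospholipase of the taste pathway, fell from 682 to 321 CPM, a log2 ratio of -1.09 (-1.13 to -1.04). Vmn2r26, a vomeronasal receptor gene, had 251 reads in WT and 0 in Spib_KO, at least 79.8-fold lower. Tas1r3, a taste receptor gene, rose from 3.72 to 13.8 CPM, a log2 ratio of 1.88 (1.49 to 2.30), and it overlaps Dvl1, whose ratio was -0.01. Of 17 measured genes for type 2 cytokine receptors and STAT signalling, 1 was lower and 0 higher, and the median of -0.39 lay at the 0.02nd percentile. The lower gene was Socs3, an inhibitor of cytokine signalling, which fell from 19.4 to 4.31 CPM, a log2 ratio of -2.17 (-2.56 to -1.81).

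Of 21 measured genes for signalling of the lymphoid type, 4 were lower and 1 higher, where the overall share gives 0.46 lower. The median was -0.20 (1.18th percentile). Was, which encodes an actin regulator of blood cells, had 200 reads in WT and 0 in Spib_KO, at least 63.6-fold lower. Coro1a, which encodes an actin-binding protein of leukocytes, had 139 and 2 reads, a log2 ratio of -5.74 (-9.11 to -4.17). Cd37, a tetraspanin gene, fell from 12.2 to 0.41 CPM, a log2 ratio of -4.81 (-6.24 to -3.84). Ptpn6 was the fourth lower gene and Ptprc the higher one. Markers of T cells, which reached at most 17.6 CPM in WT, were lower as well, with a median of -2.79. Of 15 measured genes of the ETS family in a list that leaves out Spib, 1 was lower. It was Etv5, which fell from 90 to 20 reads, a log2 ratio of -2.07 (-2.88 to -1.39). The median of that list was -0.22 (4.51st percentile).

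Genes of MHC class II, which presents peptides to CD4 T cells, were lower. Of 6 measured members 4 were lower and 0 higher, and the median of -2.12 lay below all 10000 random lists. Cd74, the invariant chain, fell 19.0-fold, from 85.8 to 4.49 CPM, a log2 ratio of -4.25 (-4.61 to -3.93). H2-Ab1 fell from 44.3 to 6.70 CPM, a ratio of -2.72 (-3.02 to -2.44), and H2-Eb1 from 14.3 to 4.95 CPM, a ratio of -1.53 (-1.90 to -1.17). H2-Aa had 281 reads in WT and 2 in Spib_KO, a log2 ratio of -6.75 (-10.1 to -5.20). Markers of T cells and intraepithelial lymphocytes moved the same way, with 4 of 5 measured members lower and a median of -2.79. They were of low abundance, at most 17.6 CPM in WT. Gzma fell from 17.6 to 1.28 CPM and Ccl5 from 12.2 to 0.76 CPM, and Cd7 and Itgae were also lower. Of 4 measured myeloid genes 1 was lower, Lyz2, which fell from 6.11 to 0.52 CPM, and no B cell, eosinophil or stromal marker was measured, with highest levels of 2.78, 4.89 and 2.44 CPM. MHC class I genes had 0 calls among 13, with a median of 0.00.

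Genes of Paneth cells, the antimicrobial cells of the crypt base, were lower in Spib_KO. Of 14 measured members 12 were lower and 0 higher, and the median of -1.92 lay below all 10000 random lists. The lysozyme gene Lyz1 fell from 553 to 154 CPM, a log2 ratio of -1.84 (-1.90 to -1.78), the defensin gene Defa24 from 1058 to 440 CPM, a ratio of -1.27, and the lectin gene Itln1 from 500.3 to 210.3 CPM, a ratio of -1.25. Others fell much further. Mptx2, a mucosal pentraxin gene, fell 27.3-fold, from 59.6 to 2.16 CPM, a log2 ratio of -4.77 (-5.30 to -4.32). Ang4, an antimicrobial ribonuclease gene, had 49.2 CPM in WT and 82.7 CPM in Spib_KO, a ratio of 0.75.

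Of 25 alpha-defensin genes in the table, on chromosome 8 between 21025545 and 21735471, 22 were measured, 20 were lower and 0 higher. Summed over the family, whose members share reads, the level was 2828 CPM in WT and 850 CPM in Spib_KO, 3.33-fold lower. Defa20 had 1470 reads in WT and 0 in Spib_KO, at least 467-fold lower, and Defa37 and Defa33 also had 0 reads, at least 140-fold and 132-fold lower. Defa2, Defa21, Defa22 and Defa5 fell 88.4-fold, 82.5-fold, 63.5-fold and 25.4-fold.

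The other antimicrobial genes of the epithelium were split, with 3 lower and 2 higher among 11 measured and a median of -0.51 (0.03rd percentile). Reg3b fell 20.8-fold, from 1939 to 93.4 CPM, a log2 ratio of -4.38 (-4.45 to -4.30). Reg3g fell 9.16-fold, from 1905 to 208 CPM, a ratio of -3.20 (-3.25 to -3.15). Both encode secreted bactericidal lectins. Nos2, the inducible nitric oxide synthase, had 92 reads in WT and 0 in Spib_KO, at least 29.2-fold lower. Sprr2a3, a small proline-rich protein gene, rose from 3.95 to 30.8 CPM, a ratio of 2.95 (2.60 to 3.34), and Duoxa2, a maturation factor of dual oxidase, from 5.72 to 20.7 CPM, a ratio of 1.85.

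Goblet cell genes had 4 of 12 measured members lower and 0 higher, with a median of -0.85 below all 10000 random lists. Muc2, the main intestinal mucin, fell from 121 to 55.4 CPM, a log2 ratio of -1.13 (-1.24 to -1.02). Zg16, Fcgbp and Ccl6 had ratios of -1.26, -1.31 and -1.48. Of 9 measured enteroendocrine genes 5 were lower and 2 higher, and the median of -2.35 lay below all 10000 random lists. The hormone genes Gcg and Cck had 316 and 379 reads in WT against 0 and 1 in Spib_KO, at least 100-fold lower for Gcg and a log2 ratio of -7.93 (-13.8 to -6.01) for Cck. Tph1, an enzyme of serotonin synthesis, had 6.83 CPM in WT and 0 reads in Spib_KO, at least 39.1-fold lower, and Sst and Chga were lower with ratios of -3.41 and -2.35. Cpe, a prohormone-processing carboxypeptidase, rose 20.9-fold, from 7.61 to 160 CPM, and the hormone gene Gip rose from 2.28 to 8.39 CPM. Enterocyte genes had 0 calls among 26, with 18 of them below 0 and a median of -0.33, also below all 10000 random lists. Fabp1, a fatty acid-binding protein gene, had 6968 and 10611 CPM, a ratio of 0.61. Stem and crypt progenitor genes had 1 of 13 lower, Nkd1, a Wnt inhibitor with a ratio of -1.78, and a median of 0.01. Of 11 measured M cell genes 1 was lower, the transcription factor gene Sox8, which fell from 6.56 to 0.23 CPM, and the median was 0.00.

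**Figure D3:**
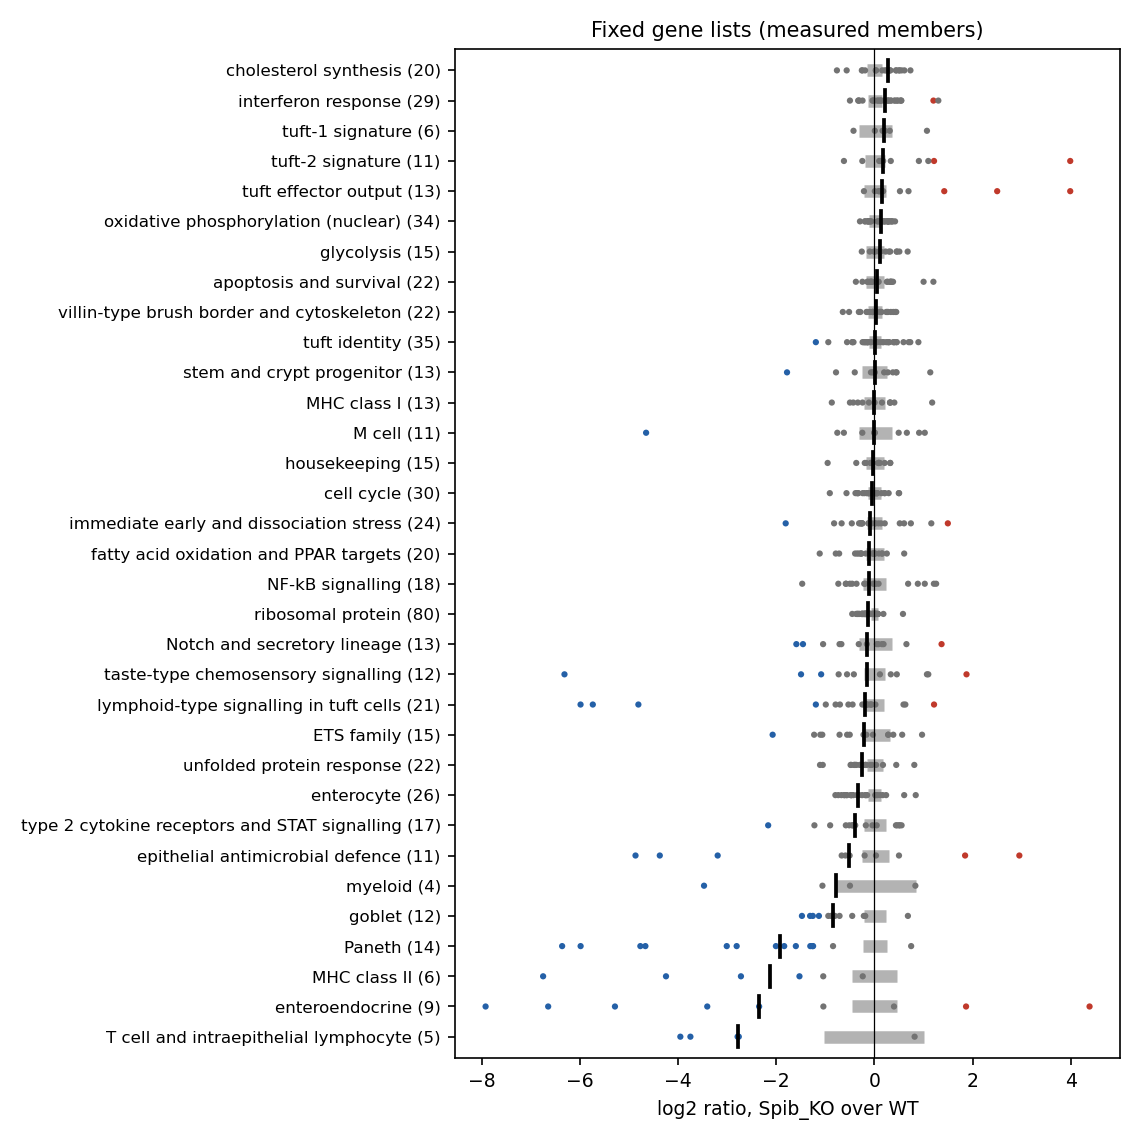
Log2 ratios of the measured members of each fixed gene list with 4 or more such members (points, red if called higher and blue if called lower in Spib_KO, grey otherwise), the list median (black bar) and the central 95% of medians of 10000 matched random lists (grey bar). The number of measured members stands after each name, and genes with 0 reads in a library are drawn at their floor. Medians were lowest for T cell (-2.79), enteroendocrine (-2.35), MHC class II (-2.12) and Paneth (-1.92) genes, and near 0 for tuft identity (0.02).

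The genes furthest above by the counting interval included several with little expression in WT. Pla2g4c, a cytosolic phospholipase A2, rose 33.4-fold, from 6.72 to 225 CPM, a log2 ratio of 5.06 (4.80 to 5.34). Ppfia2 rose 33.2-fold, Myof, a membrane repair protein gene of the ferlin family, 23.7-fold, Gdpd4 16.9-fold, Lipc, the hepatic lipase gene, 14.9-fold and Btbd16 13.0-fold. AI593442, an uncharacterised gene, had 1 read in WT and 692 in Spib_KO, a log2 ratio of 8.91 (7.02 to 14.8). Rpgrip1 rose 20.5-fold, Heatr4 20.1-fold and Prss53 18.1-fold. These last 3 overlap Supt16, Riox1 and Zfp646, whose own log2 ratios were -0.67, 0.99 and 0.10. Kit, a receptor tyrosine kinase gene of the mast cell list, rose from 85.0 to 327 CPM, a log2 ratio of 1.94 (1.86 to 2.03), while the mast cell protease genes Cpa3 and Mcpt1 had 10 and 59 reads in WT and 0 in Spib_KO.

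The genes furthest below, apart from Spib, Cck, the defensins and Mptx2, were Rgs14, Col15a1 and Plek. Rgs14, a regulator of G protein signalling, had 674 reads in WT and 0 in Spib_KO, at least 214-fold lower. Col15a1, a basement membrane collagen gene, fell 233-fold, from 129 to 0.52 CPM, a log2 ratio of -7.86 (-9.07 to -7.01). Plek, which encodes pleckstrin of platelets and leukocytes, fell 38.6-fold, from 50.6 to 1.28 CPM, a log2 ratio of -5.27 (-5.98 to -4.69).

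Broad cellular programmes had few calls and small shifts. Cell cycle genes had 0 calls among 30 and a median of -0.04. Interferon response genes had 1 call among 29, Ifit1, which rose from 23.4 to 53.9 CPM, a log2 ratio of 1.20 (1.04 to 1.37), and overlaps Ifit1bl1, with a ratio of -0.32. Their median was 0.21 (99.6th percentile). None of 20 cholesterol synthesis genes and 34 oxidative phosphorylation genes was called, with medians of 0.27 and 0.14 (99.9th and 99.2nd percentile). None of 22 unfolded protein response genes and 80 ribosomal protein genes was called either, with medians of -0.25 and -0.14 (0.14th and 0.03rd percentile). Among 24 immediate early and dissociation stress genes the heat shock gene Hspa1a rose 2.82-fold, Ier3 fell with a ratio of -1.81, and the median was -0.09. Among 13 Notch and secretory lineage genes Jag2 rose with a ratio of 1.37, Foxa3 and Dll4 fell with ratios of -1.59 and -1.46, and the median was -0.15. NF-kB, glycolysis, fatty acid oxidation, apoptosis and brush border genes had 0 calls among 18, 15, 20, 22 and 22, with medians of -0.11, 0.12, -0.11, 0.06 and 0.03. The 15 housekeeping genes had 0 calls and a median of -0.03, which was 0.08 when ribosomal protein genes were left out. Of the most abundant genes, Krt18 had 27027 and 31923 CPM, Krt8 14958 and 16280 CPM and Actb 9279 and 10024 CPM, with log2 ratios of 0.24, 0.12 and 0.11. Dmbt1 and Crip1 had ratios of -0.45 and 0.46. None of the 2 measured group 2 innate lymphoid cell genes, Il9r and Areg, was called, with ratios of 0.32 and -0.57. Haemoglobin genes Hba-a1 and Hba-a2 had ratios of -0.42 and -0.44, with 0 calls among 3 erythroid genes.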

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

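Scaling by DESeq2 size factors, total counts, the upper quartile or totals without the 20 most abundant genes shifted log2 ratios by -0.012 to 0.009 and kept both counts of called genes within 1.5 times of 250 higher and 233 lower. The same held for scaling on the tuft identity list, a prior count of 5, thinning of the deeper library, and removal of ribosomal protein and haemoglobin genes. Deposited TPM gave 203 higher and 256 lower, of which 163 and 163 were also called from counts. TPM and FPKM carry no counting interval. Their rule was a log2(value + 1) difference of at least 1, among genes with a value of 5 or more in at least 1 library. The nearest rule on counts is the point estimate, with 425 higher and 419 lower, so the TPM counts are not like for like with 250 and 233. The counts moved further where the rule itself changed: without the expression filter they were 595 higher and 716 lower, with a CPM minimum of 20 they were 101 and 106, by the point estimate they were 425 and 419, and at a 4-fold bound 65 and 88. These follow from how many genes each rule admits. With deposited FPKM 165 genes were higher; the cause was not tested. An alternative chosen after seeing the data, without genes of the lists of other cell types and without defensins, left 247 higher and 192 lower. The log2 ratio of Spib was -6.97 to -6.82 under the alternatives on counts, and -6.22 and -6.06 as log2(value + 1) differences of TPM and FPKM, where the added 1 pulls the low Spib_KO value up. No named gene that was called and no list median outside the central 95% of random lists changed sign under any alternative run. Among all list medians 21 of 428 values changed sign, in 9 lists. Of 66 named genes called in the main analysis, all stayed called under DESeq2 size factors and total counts. Etv5 was no longer called with the upper quartile, Nos2 and Etv5 with thinning, and 4 genes with TPM (Sox8, Itgae, Nos2 and Etv5). With FPKM 10 were lost (Ppfia2, Myof, Tas1r3, Slc18a3, Tph1, Sox8, Itgae, Nos2, Etv5 and Dll4). With the CPM minimum of 20, which 23 of the 66 do not reach, 43 stayed. Leaving out a replicate was not possible with 1 library per genotype. No paired analysis was possible because each genotype has 1 library. At this depth 3 counts correspond to 0.167 CPM in WT and 0.175 CPM in Spib_KO. The robust SD of log2 ratios was 0.60 for genes with a mean CPM of 5 to 20 and 0.27 from 100 to 500, so small differences of low genes carry little information.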

Other observations

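Of the tests in this part, those of the further Paneth genes and of the intestinal segments were set before the values they use were seen, and the others afterwards, as was the range when a gene is left out. The genes of those 2 tests were chosen before their values were seen, and the other genes named here outside the rule for names afterwards.

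Some single genes of the intestinal epithelium were higher in Spib_KO. They were picked because they rose, and the fixed lists went the other way, with 0 of 26 enterocyte genes and 0 of 12 goblet cell genes higher and medians of -0.33 and -0.85. The gasdermin genes Gsdmc2, Gsdmc3 and Gsdmc4, neighbours on chromosome 15 whose reads may be partly shared, rose 5.61-fold, 4.88-fold and 4.95-fold, with 140, 35.4 and 213 CPM in Spib_KO. The ileal bile acid-binding protein gene Fabp6 rose from 19.1 to 97.8 CPM and the carbonic anhydrase gene Car2 from 28.5 to 176 CPM. The chloride channel accessory genes Clca3a1 and Clca3a2 rose 4.82-fold and 5.22-fold, and B3gnt6, a mucin core glycosyltransferase gene, 8.67-fold. Sprr2a1 rose from 124 to 436 CPM. Fgf15, the ileal hormone of bile acid feedback, had 0 reads in WT and 105 in Spib_KO, at least 36.7-fold higher, and Epgn, a growth factor gene, had 1 and 309 reads, a log2 ratio of 7.75 (5.85 to 13.6). Because Fabp6 and Fgf15 are genes of the ileum, a candidate explanation is that the Spib_KO sort held more cells from distal intestine. Other distal genes (Osr2, Slc51a, Slc51b and Cubn) had a median log2 ratio of 0.29 and proximal genes (Gata4, Pdx1, Slc40a1 and Slc46a1) 0.05. The difference of 0.238 (0.18 to 0.30 when a gene of either list is left out) lies under the value of 1 set beforehand for this explanation. That argues against a shift of the whole sort large enough to move these genes by that much. It does not decide whether a few distal cells were carried along. The genes of the 2 lists already had 8.5 to 147 CPM in WT, while Fgf15 had 0 reads. A change in the tuft cells that follows the loss of Spib, and a difference between the animals unrelated to it, stay open as untested.

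Several further genes known from leukocytes were lower in Spib_KO. Pstpip1 fell from 89.1 to 8.16 CPM, Adgre5 from 74.8 to 9.91 CPM, Prkcb from 30.1 to 2.45 CPM, Fgd2 from 24.4 to 1.98 CPM and Clec4a1 from 21.2 to 1.98 CPM, beside Plek. More leukocytes in the WT sort could lower them, but leukocytes would bring their abundant transcripts too. In WT, the pan-leukocyte genes Cd52, Srgn, Laptm5, Arhgdib and Ptprcap had 0.67, 0.94, 2.33, 0.67 and 1.17 CPM, and Coro1a, the highest of 10, had 7.72 CPM. All 10 had fewer reads in Spib_KO (median 0.81 CPM in WT and 0.15 CPM in Spib_KO), though only Coro1a, at 0.12 CPM there, was measured and passed the rule. Among markers of T cells, Ccl5 fell from 12.2 to 0.76 CPM and Gzma, the leukocyte marker that lost most, from 17.6 to 1.28 CPM, and Cd74, which leukocytes and epithelium express, fell from 85.8 to 4.49 CPM. The 6 genes lost 2.36 times as much as Gzma (median), between the values set for and against. The gap to the pan-leukocyte genes was wider, with a median loss of 38.48 CPM for the 6 genes and 0.55 CPM for those 10. Since only Coro1a of the 10 was measured and the outcome depends on the marker compared, leukocytes stay open. Uneven amplification of single genes stays open. Of 10000 matched random lists, 0.23% held as many lower genes as the lymphoid-type list. That list was singled out among 38, which brings the figure to 8.74%. The random lists were drawn from the same 2 libraries, so this share is not a p-value and does not measure amplification. The 6 genes were also picked because they fell. An effect of the loss of Spib and a difference between animals stay open as untested.

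Most Paneth genes fell, by unequal amounts, while Ang4 had a log2 ratio of 0.75. Fewer Paneth cells carried along in the Spib_KO sort, which selects against them with Siglec-F, may account for genes such as Lyz1 that fell about 2- to 4-fold. The 4 measured further Paneth genes went both ways (Clps -1.19, Habp2 -2.48, Pnliprp2 0.84 and Fgfbp1 0.11). Their median of -0.54 lay between the values set for and against, so fewer Paneth cells cannot be told apart from a change within cells. The filter left out Wnt3 (33 reads in WT and 1 in Spib_KO) and Sntb1 (1 and 0). With both included the median was -1.38, past the value set for fewer Paneth cells, so the outcome depends on the filter. That median rests in part on Sntb1, whose ratio comes from 1 read and the prior count of 0.5. For the 9 Paneth genes that fell over 16-fold, fewer Paneth cells stay open as well, because the test could not decide. All 9 had an interval below that of Lyz1 by 1 or more on the log2 scale, but they were picked for their fall. The value set against needed 2 such genes outside the defensin family, and only 1 of the 9, Mptx2, lies there. Defensins share reads, and their sum fell 3.33-fold, beside 3.58-fold for Lyz1. A strain difference in the defensin cluster, where 8 of 22 measured genes fell that far and 0 were higher, was not tested, since no genotype of the cluster was used here. Reg3b, Nos2 and Mptx2, also over 16-fold lower, lie on chromosomes 6, 11 and 1, outside that cluster.

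Adh1, an alcohol dehydrogenase gene, fell from 4429 to 1458 CPM, and Reg4, a secreted lectin gene, from 91.4 to 12.4 CPM. Between 175 and 180 Mb of chromosome 2, 8 of 26 measured genes were lower and 1 higher, the most in any 5 Mb window after that of the defensins on chromosome 8, and they include the zinc finger genes Zfp970 (166 to 39.2 CPM) and Zfp967 (18.1 to 0.93 CPM), whose family members share sequence. For Dclk1 the count and the deposited TPM differed: the log2 ratio was -0.17 from counts and -0.71 from TPM (1324 to 811), so the effective transcript length behind the TPM, relative to that of the median gene, was 1.43 times as long in Spib_KO. For Plcb2 it was 1.36 times as long. Of 8088 measured genes with at least 100 reads and a TPM of 5 in both libraries, 33 had lengths that differed by 1.3-fold or more, and these 2 were the only ones of them with 3000 reads or more in a library.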
